A study of Mus musculus with 6 samples.

How the data were processed

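RNA of mouse bone marrow mesenchymal stem cells at passage 6 to 12 was analysed in 6 libraries, 3 from cells given a control siRNA and 3 from cells given an siRNA against Dia2 at 50 nM. Per the labels' protocols, cells adhered for 24 h, were transfected overnight with a lipid reagent, and were harvested 24 h after a change of medium, with column-purified RNA sequenced on an Illumina instrument. Groups and replicate numbers were taken from the sample titles. The sequence of the control siRNA is not given in the sources used here.

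The deposited table has 1 row per gene and, per the file headers, a gene count and an RPKM value for each library, with a coding length. Per the submitters' processing notes the tools were bcl2fastq, TopHat2 2.0.6 and HTSeq, named with no role or order, and the builds were hg19 and GRCh37, which are human. The table itself holds mouse symbols and mouse chromosomes, and of 20762 rows with a matching symbol 99.3% overlapped the gene of that symbol in GRCm38.p6, so its coordinates were read as GRCm38. The annotation, the strand setting and the treatment of reads with several matches are not given in the sources used here. Without a stated strand, counts of overlapping and antisense genes cannot be told apart, and those of near-identical copies may be shared. The deposited counts are whole and all even, with 0 odd values in 23358 rows, as if each fragment added 2. The deposited RPKM values equal the count divided by the coding length and by 1 total per library, of which the listed genes hold 82.6% to 85.8%. They were used only for this check, and all tests used the counts. Older symbols were replaced by the current ones for 1919 rows, and 4858 rows had no count in any library.

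Total counts ranged from 70538768 to 110006338 per library. A floor of 6 counts (3 fragments, if each added 2) corresponds to 0.0545 to 0.0851 CPM, which limits statements about scarce genes and covers counting error only, since the reads carry no molecular identifiers. To look for libraries entered more than once, halved counts of the replicates of a group were compared by chi-square. The statistic per degree of freedom ranged from 7.04 to 90.66, so no pair agreed within sampling noise and all 6 libraries were kept.

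The choices that follow were fixed before the data were examined unless stated otherwise. Genes were filtered with filterByExpr (a minimum of 10 counts in a library and 15 in total, scaled to library size) and normalised with TMM factors, which also scale the CPM values. The Dia2 group was compared with the control group by edgeR's quasi-likelihood test with robust dispersion estimates (edgeR 4.0.16, limma 3.58.1, R 4.3.3), with no other term in the model and Benjamini-Hochberg adjustment at 0.05. The standard error of a log2 fold change was its absolute value divided by the square root of the F statistic. Gene lists, 28 in number, were tested with camera at a preset inter-gene correlation of 0.01 where at least 5 members passed the filter, which held for 27, with adjustment over the lists. A list and a gene of another list are not reported here. Camera with an estimated correlation and fry served as alternatives. Fry tests whether the members of a list move on balance one way and does not compare them with other genes.

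The genes named are Diaph3, then, whatever their p, Diaph1, Diaph2, Lmna, Lmnb1, Lmnb2, Runx2, Sp7, Alpl, Bglap, Spp1, Pparg, Adipoq and Fabp4. To these were added the 12 genes with the largest rises and the 12 with the largest falls among those with an adjusted p under 0.05, a mean CPM of at least 2, no overlap between groups and no predicted or clone name. From each list up to 4 members past the threshold with the largest change could be named; other members are given to describe their list.

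The alternatives tried were DESeq2 size factors, upper-quartile factors and no composition factor; no filter beyond 1 count and a mean CPM of at least 1; DESeq2 1.42.0 and limma-voom; the replicate number as a block; and each library left out in turn. Chosen after seeing the data were halved counts, a fit without Rn45s and Lars2, and a fit without the library of each group richest in Rn45s. So were lowess offsets for transcript GC content and the deposited coding length (both known for 98.6% of the tested genes). A fit without genes that hold certain 3′ UTR words was also chosen then. The 6 libraries were also split in all 10 ways into 3 and 3.

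The position of the siRNA was found by matching its sequence to GENCODE M21 transcripts (GRCm38). The planned seed test took the target of bases 2 to 8 of the antisense strand, AACTTAA, and compared the median log2 fold change of genes with and without it in an annotated 3′ UTR, against 104 permutations of the same bases. After the fold changes had been seen, all 7-base words were scanned in the same way. For 9810 genes with a 3′ UTR and a mean CPM of at least 5, log2 fold changes limited to ±2 were adjusted for 3′ UTR length and AT content by a quadratic fit, and each of 16289 words found in at least 30 genes was given the mean of the adjusted values and a z (that mean over its standard error). Genes were then divided at random into a part in which the words were found and a part in which they were tested. Shares of genes carry 95% Wilson intervals. Genes are not independent replicates, so a z describes these libraries and is no test across cultures.

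The steps were tested on simulated data before use. Counts were drawn for the 14151 filtered genes from their means, dispersions and library sizes, with genes changed by known folds and the extracellular matrix list raised 1.5-fold. In this simulation of the comparison edgeR recovered 22 of 50 genes changed 1.25-fold, 35 of 50 changed 1.5-fold, 44 of 50 changed 2-fold and 49 of 49 changed 4-fold, with 17 calls among 13917 unchanged genes, and camera called 1 list, the raised one. The genes were drawn independently, so the simulation could not show how camera behaves when the genes of a list vary together. Far fewer genes were changed than passed in the data, so these rates may not hold there. In shuffled fold changes of 9810 genes with 0.2 subtracted from the genes of a chosen word, the scan ranked that word first in 3 of 3 trials, and without subtraction z ran from -3.55 to 4.22.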

Results

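Gene expression was measured by RNA sequencing in mesenchymal stem cells grown from the bone marrow of C57BL/6 mice, which are adherent progenitors able to form bone, fat and cartilage cells. The cells were transfected either with a control siRNA or with an siRNA against Dia2, also written mDia2. Dia2 is the product of Diaph3 (listed under the older symbol Diap3) and belongs to the formins, proteins that nucleate and lengthen unbranched actin filaments. The siRNA was given at 50 nM and RNA was collected 24 h after the transfection medium had been replaced. The 6 libraries formed 2 groups, 3 with control siRNA and 3 with Dia2 siRNA. The labels do not say whether the 3 libraries of a group came from separate cultures, so the p-values measure only the spread between these libraries, which may be technical.

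The gene counts summed to 110006338, 80390882 and 70538768 in control replicates 1, 2 and 3, and to 78529650, 95573070 and 91953694 in Dia2 replicates 1, 2 and 3. Every count in the table was an even number, so each sequenced fragment seems to have been counted as 2, and the number of independent observations is at most each total divided by 2. The ribosomal precursor Rn45s held 6.05%, 6.0% and 11.7% of the counts in control replicates 1, 2 and 3, and 10.9%, 7.41% and 6.05% in the Dia2 replicates, so its high values occurred in 1 library of each group. The comparison asks which transcripts of these stem cells change when Dia2 is lowered.

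The targeted gene was lower in every library of the Dia2 group. Here and below, CPM values (counts scaled to library size by the TMM factors) are means ± SD over 3 libraries, log2 fold changes carry their SE, and adjusted p-values come from edgeR. Diaph3 stood at 84.7, 80.1 and 84.8 CPM in the control replicates and at 7.52, 8.37 and 7.39 CPM in the Dia2 replicates. The mean fell from 83.2 ± 2.7 to 7.76 ± 0.532 CPM (SD, n = 3 each), a log2 fold change of -3.42 ± 0.07 (SE; adjusted p = 1.66e-11), or 10.7-fold. The stated siRNA sequence, CAGAGTCCATGATTCAGAACTTAAT, matched the sense strand of Diaph3 in the GRCm38 transcripts without a mismatch. In transcripts Diaph3-201 and Diaph3-202 its first 17 bases lie in coding exon 19 (chromosome 14, 86910029 to 86910045, minus strand) and its last 8 bases in coding exon 20 (86906031 to 86906038). The other Diaph genes, Diaph1 and Diaph2, moved little. Diaph2 was 1.19-fold lower (log2 fold change -0.25 ± 0.07, adjusted p = 0.00733), and Diaph1 did not pass the test (-0.07 ± 0.04, adjusted p = 0.173), although it passed without control replicate 3 (-0.11, adjusted p = 0.00431).

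**Figure D1:**
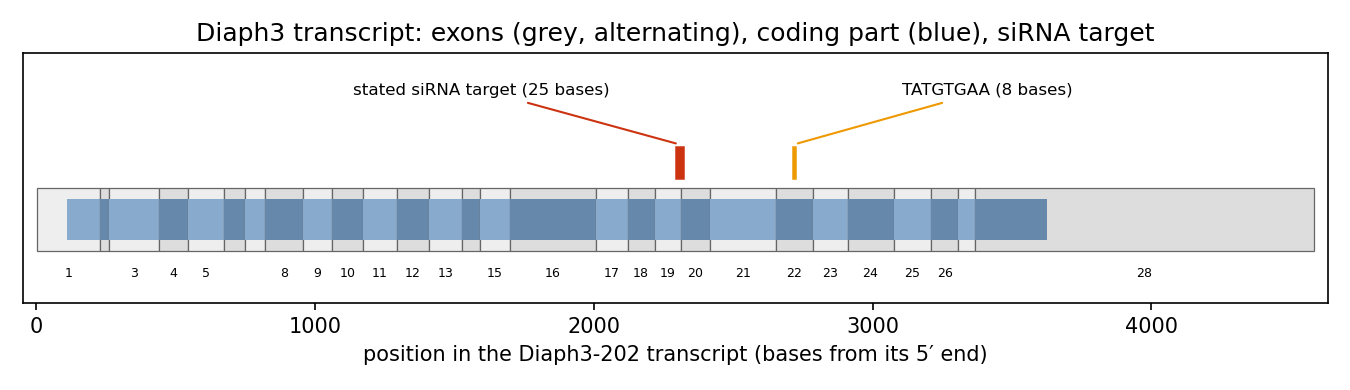
Map of the Diaph3-202 transcript (GRCm38), with position in bases from its 5′ end on the horizontal axis, exons as alternating grey boxes numbered below and the coding part in blue. The red bar marks the 25-base siRNA target, which starts at base 2296 and spans exons 19 and 20; the orange bar marks the 8-base word TATGTGAA at base 2713 in exon 22.

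Expression differed between the groups over much of the transcriptome, mostly by small amounts. Of 14151 genes tested, 8380 passed an adjusted p of 0.05, with 4145 higher and 4235 lower with Dia2 siRNA. Among these, 823 were higher and 391 lower by at least 2-fold, and 158 were higher and 67 lower by at least 4-fold. Many of these genes were scarce, and with a mean CPM of at least 1 required 693 in place of 1214 changed at least 2-fold. The median absolute log2 fold change of the genes past the threshold was 0.435. The 3 libraries of one group all lay above the 3 of the other for 9139 genes, 64.6% of those tested, where chance gives 10%. Correlations of log2 CPM were 0.993 to 0.995 within groups and 0.977 to 0.978 between them, and the first principal component, which separated the groups, held 70.9% of the variance. The biological coefficient of variation was 0.073, so changes far below 2-fold passed the test.

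The largest rises included genes that were nearly silent in the control cells. Anxa8, an annexin that binds calcium and phospholipid, rose 22.1-fold from 2.39 ± 0.358 to 52.7 ± 1.29 CPM (SD, n = 3 each; log2 fold change 4.47 ± 0.09, adjusted p = 2.48e-11). Dio3, the deiodinase that inactivates thyroid hormone, rose 10.9-fold, Ckmt1, a mitochondrial creatine kinase, 11.8-fold, and Serpinb1a, a serine protease inhibitor of a family with close paralogs, 9.69-fold. Among abundant transcripts, Fbn1, which encodes the microfibril protein fibrillin-1, rose 6.84-fold from 177 ± 3.71 to 1210 ± 16.9 CPM, and Exoc4, a subunit of the exocyst complex, rose 7.23-fold from 29.9 ± 2.9 to 216 ± 4 CPM. The microfibril-associated Mfap5 rose 6.56-fold and the matrix glycoprotein gene Tnn 6.02-fold. Pik3ip1, Car3, Insc and Vnn1 completed the 12 largest rises, with 5.75- to 6.84-fold changes. The 3′ UTRs of Fbn1, Exoc4 and Pik3ip1 hold the 7-base word GCAGTAC.

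The largest fall was that of Diaph3 itself. Rgs16, a regulator of G-protein signalling, fell 9.44-fold from 14.5 ± 0.573 to 1.54 ± 0.225 CPM (log2 fold change -3.24 ± 0.1, adjusted p = 4.53e-10). Ppif, which encodes cyclophilin D of the mitochondrial permeability pore, fell 7.27-fold, and Acsl4, an acyl-CoA synthetase that prefers arachidonic acid, fell 6.95-fold from 274 ± 31.2 to 39.4 ± 1.39 CPM. Mrap, the accessory protein of melanocortin receptors, fell 5.89-fold. Rbm47 and Mbnl3, both RNA-binding proteins, fell 5.76-fold and 5.43-fold, and Tmprss11f, Marcksl1 and Ptpn5 fell 5.52-, 5.27- and 5.26-fold. Prl2c2 and Prl2c3 also stood among the 12, at 6.94- and 7.05-fold lower, but they are near-identical copies of each other and reads may have been split between them. Apart from Diaph3, 8 of these genes (Acsl4, Marcksl1, Mbnl3, Mrap, Ppif, Rbm47, Rgs16 and Tmprss11f) hold the 7-base word TATGTGA or ATGTGAA in the 3′ UTR.

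Lamin B1 mRNA was strongly lower, and other genes of the nuclear lamina and envelope moved both ways. Lmnb1, a structural protein of the lamina, fell 5.05-fold from 215 ± 8.84 to 42.6 ± 1.4 CPM (log2 fold change -2.34 ± 0.05, adjusted p = 2.48e-11), with 225, 210 and 209 CPM in the control replicates and 44.0, 41.3 and 42.4 in the Dia2 replicates. Lmnb2 fell 1.31-fold (-0.39 ± 0.07, adjusted p = 0.000275), and Lmna did not pass the test, at 687 ± 48.9 and 724 ± 12.7 CPM (0.07 ± 0.05, adjusted p = 0.261). Of 19 members tested, 6 were higher, 7 lower and 6 not past the threshold, with the same counts when adjusted over the list alone. Tmpo, Lbr, Syne1 and Syne2, which encode proteins of the inner or outer nuclear membrane, fell at log2 fold changes of -0.50, -0.34, -0.50 and -0.38. Sun1 and Sun2, whose products link the lamina to those of the Syne genes, rose at 0.72 and 0.47. The list as a whole did not pass (camera adjusted p = 0.307; 0.447 with an estimated correlation). The study is known to have followed lamin B1, and the list was written with that in mind, so its members are not independent evidence. The annotated 3′ UTR of Lmnb1 holds the 8-base word TATGTGAA (chromosome 18, 56752749 to 56752756, GRCm38), and a further copy lies over its stop codon (56752642 to 56752649). The 3′ UTR of Tmpo holds ATGTGAA, and that of Sun1, which rose, holds TATGTGA.

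Among 13 formins tested, 3 were higher and 4 lower. Besides Diaph3 and Diaph2, Fhod1 (-0.63) and Fmnl3 (-0.29) fell, while Daam2 rose 1.98-fold, Fhdc1 1.62-fold and Fmn1 at a log2 fold change of 0.13. The list did not pass (camera adjusted p = 0.178). Members of the Arp2/3 complex and the regulators that start branched actin networks were lower more often than higher, 11 against 2 of 20. Arpc1a fell 1.78-fold and Wasf1 1.72-fold, Arpc1b rose at a log2 fold change of 0.55, and Wasf3, present near 1 to 2 CPM, rose 2.27-fold (camera adjusted p = 0.178). Of 30 targets of SRF and MRTF, the transcription factors that respond to actin assembly, 7 were higher and 15 lower. Fhl1 rose 2.58-fold, Cnn2 fell 1.67-fold, and both cytoplasmic actins, Actb (-0.47) and Actg1 (-0.33), were lower (camera adjusted p = 0.581). The counts of these 3 lists were the same when adjusted over each list alone. The 3′ UTRs of Diaph2, Wasf1 and Cnn2 hold ATGTGAA, whereas those of Fhod1 and Arpc1a hold neither it nor TATGTGA.

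Regulators and markers of bone formation were mostly higher. Runx2, a transcription factor needed for osteoblasts, rose 2.02-fold from 49.7 ± 2.86 to 101 ± 1.48 CPM (log2 fold change 1.02 ± 0.05, adjusted p = 1.51e-08), and the alkaline phosphatase gene Alpl rose 2.39-fold from 3.05 ± 0.282 to 7.29 ± 0.618 CPM (adjusted p = 8.32e-07). Bmp4, a bone morphogenetic protein, rose 3.77-fold. Sp7, which acts with Runx2, rose at 3.16 ± 0.52 on the log2 scale from very low counts of 12, 0 and 10 to 52, 82 and 68. Bglap2, an osteocalcin gene with close copies, had 2, 2 and 0 counts in the control and 10, 12 and 14 in the Dia2 libraries, and Bglap itself was too low to test, with 8, 4 and 2 against 2, 10 and 10. Spp1, which encodes the matrix protein osteopontin and was among the most abundant transcripts named here, fell 1.92-fold from 5200 ± 265 to 2710 ± 61.6 CPM (-0.94 ± 0.05). Tnfsf11, the osteoclast factor RANKL, also fell (-1.45), but was scarce and close to the floor, at 0.265 ± 0.0718 and 0.095 ± 0.0373 CPM. Of 23 osteoblast genes tested, 14 were higher, 2 lower and 7 not past the threshold, both over all genes and adjusted over the list alone (camera adjusted p = 0.000342; adjusted p = 0.101 with an estimated correlation). One of them, Bmp2, lay near 0.1 CPM and lost its call without control replicate 2 or 3 or without any Dia2 replicate (log2 fold change 1.71, and 1.26 to 1.81 without them). Osteogenesis is also a subject of the study, so this list is not independent evidence either. The 3′ UTR of Runx2 holds GCAGTAC once.

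Genes of fat cells were lower more often than higher. Pparg, the transcription factor that directs adipocyte formation, fell 1.49-fold from 82.9 ± 1.68 to 55.7 ± 0.482 CPM (log2 fold change -0.57 ± 0.04, adjusted p = 3.9e-07). The fatty acid carrier Fabp4 fell 2.16-fold, lipoprotein lipase (Lpl) 1.82-fold and the lipid droplet protein gene Plin4 1.69-fold. Adipoq, which encodes adiponectin, did not pass at 2.49 ± 0.0842 and 3.02 ± 0.377 CPM (0.28 ± 0.13, adjusted p = 0.0768), but passed without Dia2 replicate 2 (0.37, adjusted p = 0.0442). Of 21 members, 2 were higher and 8 lower, also when adjusted over the list alone (camera adjusted p = 0.0132; adjusted p = 0.343 with an estimated correlation). Among cartilage genes, the collagens Col2a1 and Col11a1 rose 4.32-fold and 3.78-fold and the transcription factor Sox9 1.72-fold, while Col11a2 fell 1.98-fold. In this list 5 of 10 members were higher and 1 lower, also adjusted over the list alone (camera adjusted p = 0.00208; adjusted p = 0.101 with an estimated correlation; 0.126 without control replicate 3).

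**Figure D2:**
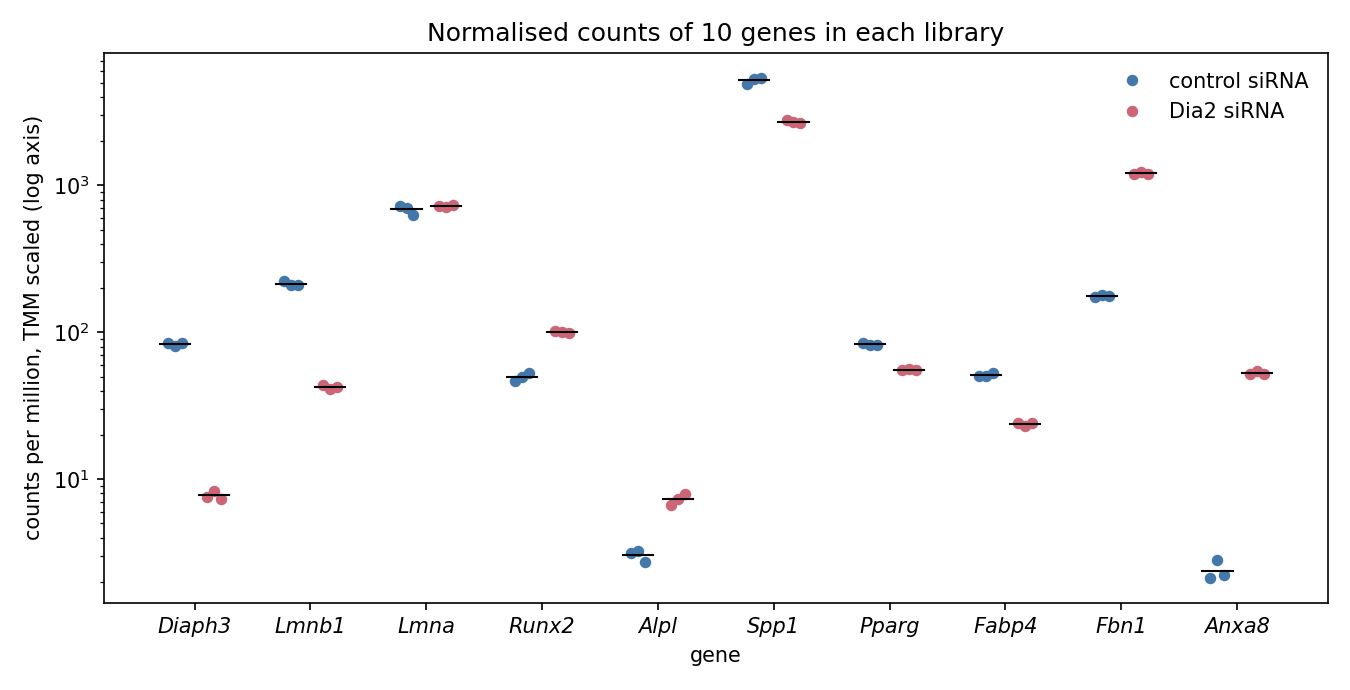
Normalised counts (CPM with TMM scaling, logarithmic axis) of 10 genes in each library, with control siRNA in blue and Dia2 siRNA in red; each point is 1 library and each black line the mean of 3. The groups do not overlap for any gene shown except Lmna, and Diaph3 falls from a mean of 83.2 to 7.76 CPM.

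Genes of the extracellular matrix were mostly higher. Of 35 tested, 26 were higher, 3 lower and 6 not past the threshold, and 27 were higher when adjusted over the list alone. Beside Fbn1, the metalloproteinase inhibitor gene Timp3 rose 4.62-fold from 89.5 ± 4.71 to 414 ± 9.87 CPM, the matricellular Postn 3.44-fold and the elastic fibre gene Fbln5 2.89-fold. The main fibrillar collagens rose less, with Col1a1 at 0.51, Col1a2 at 0.48 and Col3a1 at 0.55 on the log2 scale, and Thbs2, Col6a3 and Loxl1 fell. The list had a camera adjusted p of 1.23e-13, and an adjusted p of 0.101 with an estimated correlation. Of 28 focal adhesion genes 13 were higher and 6 lower. The collagen receptor integrins Itga11 and Itga1 rose 5.23-fold and 2.5-fold and Tln2, a talin, 2.55-fold, whereas Vasp, an actin regulator, fell (-0.75). Their camera adjusted p of 0.0132 became 0.447 with an estimated correlation and 0.209 without control replicate 3.

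In the lists of Wnt, TGF-beta, YAP and TAZ, and BMP targets more genes were higher than lower. Of 18 genes tested in the Wnt target list 13 were higher and 1, Myc, lower. The list also holds Dkk and Sfrp genes, families of secreted Wnt regulators, so its rises are not all a measure of Wnt output. The matricellular Ccn5 rose 5.08-fold from 36.9 ± 1.58 to 187 ± 6.58 CPM, Dkk3 rose 5.03-fold, and the feedback regulator Axin2 and the receptor gene Lgr5, both under 3 CPM, rose 4.68-fold and 4.14-fold (camera adjusted p = 1.1e-08; adjusted p = 0.0718 with an estimated correlation). Of 20 TGF-beta targets 15 were higher and 2, Tgfbi and Snai2, lower, with Ltbp2 2.61-fold higher (camera adjusted p = 0.0017; adjusted p = 0.382 with an estimated correlation). Of 22 YAP and TAZ targets 12 were higher and 3 lower, led by Ccdc80 at 2.94-fold and the coagulation factor gene F3 at 2.12-fold, whereas the often used targets Ccn1, Ccn2 and Ankrd1 did not pass, at -0.05, 0.08 and -0.05 (camera adjusted p = 0.0183; adjusted p = 0.343 with an estimated correlation; 0.175 without control replicate 3). Of 12 BMP targets 9 were higher and 1 lower, with Smad9 1.78-fold higher, and the list did not pass (camera adjusted p = 0.129), although it did without control replicate 1 (0.0337). Counts adjusted over the focal adhesion, Wnt, TGF-beta, YAP and TAZ and BMP lists alone were the same.

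Surface and stromal markers of mesenchymal stem cells were higher in 14 of 17 genes and lower in 1, Nes. The surface antigen gene Ly6a (Sca-1) rose 3.54-fold, the adhesion molecule gene Alcam 3.2-fold and the chemokine gene Cxcl12 2.57-fold from 815 ± 126 to 2100 ± 72.6 CPM (camera adjusted p = 5.12e-06; adjusted p = 0.0774 with an estimated correlation). Smooth muscle and pericyte markers were higher in 7 of 13 and lower in 1, with Cspg4 2.71-fold and Notch3 1.66-fold higher (camera adjusted p = 0.0339; adjusted p = 0.457 with an estimated correlation; 0.0734 without control replicate 3). Markers of other cell types were scarce. Of 7 blood and macrophage markers tested 1 was higher and 4 lower, among them Cd53, which fell 5.08-fold from 3.41 ± 0.34 to 0.675 ± 0.224 CPM, and Itgb2, which fell 2.97-fold from 2.65 ± 0.394 to 0.892 ± 0.17 CPM (camera adjusted p = 0.146, and 0.0372 with genes of a mean CPM of at least 1). Of 6 endothelial markers 1 was higher and 1, Kdr, lower at 1.15 ± 0.121 and 0.646 ± 0.143 CPM (camera adjusted p = 0.849). In these 4 lists the counts adjusted over the list alone were the same.

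Genes of DNA replication and of the cholesterol pathway were mostly lower. Of 30 G1/S and replication genes none rose and 21 fell over all genes tested (1 higher and 21 lower when adjusted over the list alone), each by less than 2-fold. The licensing factor gene Cdt1 fell 1.59-fold from 45 ± 6.22 to 28.4 ± 0.605 CPM, the helicase subunit gene Mcm5 1.46-fold and the flap endonuclease gene Fen1 1.44-fold (camera adjusted p = 0.00315; adjusted p = 0.492 with an estimated correlation). Of 30 mitosis and cytokinesis genes 9 were higher and 7 lower (9 and 6 adjusted over the list alone), from Nusap1 at 0.53 to Bub1 at -0.26, with no call for the list (camera adjusted p = 0.581). Of 23 genes of cholesterol synthesis and uptake 18 were lower and 1, Sc5d, higher, also adjusted over the list alone. Stard4, a sterol carrier, fell 3.85-fold from 94.4 ± 8.98 to 24.5 ± 1.1 CPM, Fdft1, which makes squalene, 1.67-fold, and Lss, which cyclises its epoxide, 1.63-fold (camera adjusted p = 1.37e-05; adjusted p = 0.101 with an estimated correlation). The 3′ UTRs of Stard4, Lss, Cdt1 and Fen1 hold ATGTGAA, whereas those of Fdft1 and Mcm5 hold neither it nor TATGTGA.

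Stress and immune lists were mixed and did not pass. Of 24 p53 targets 11 were higher and 8 lower, with the death receptor gene Fas 2.49-fold higher, Zmat3 2.32-fold lower, and Cdkn1a (-0.17) and Mdm2 (-0.42) lower (camera adjusted p = 0.418). Of 22 genes of ER stress and the amino acid response 7 were higher and 7 lower, with Chac1 2.34-fold and Hyou1 1.8-fold higher. For this list the median was -0.024 while the mean was 0.159 and the test pointed up (camera adjusted p = 0.211). Of 23 hypoxia and glycolysis genes 8 were higher and 7 lower, with Bnip3 1.92-fold higher and hexokinase 2 (Hk2) 2.1-fold lower (camera adjusted p = 0.581). Of 30 interferon-stimulated genes 11 were higher and 3 lower; Oasl1 and Rsad2 fell 3.88-fold and 3.07-fold from near 1 CPM and Ifit3b rose 2.47-fold (camera adjusted p = 0.566). Of 17 inflammatory genes 8 were higher and 5 lower, or 9 and 5 adjusted over the list alone. In that list Ptgs2, the inducible cyclooxygenase, fell 2.36-fold from 69 ± 8.34 to 29.2 ± 0.926 CPM, Il6 fell from 0.471 ± 0.048 to 0.0719 ± 0.0496 CPM, with 2, 12 and 6 counts in the Dia2 libraries, and the collagenase gene Mmp13 rose 3.77-fold (camera adjusted p = 0.581). The 14 genes of the microRNA and RNA interference machinery, which siRNA itself uses, included 7 higher and 2 lower, with the Argonaute genes Ago4 2.92-fold and Ago2 1.44-fold higher (camera adjusted p = 0.101). Unless stated, counts adjusted over these lists alone were the same. The 3′ UTRs of Zmat3, Ptgs2 and Rsad2 hold TATGTGA or ATGTGAA, as do those of Fas and Ago4, which rose. That of Ago4 also holds GCAGTAC. Those of Hk2, Il6 and Oasl1 hold neither TATGTGA nor ATGTGAA. The mitochondrially encoded genes had no rows in the table used here and were not analysed.

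**Figure D3:**
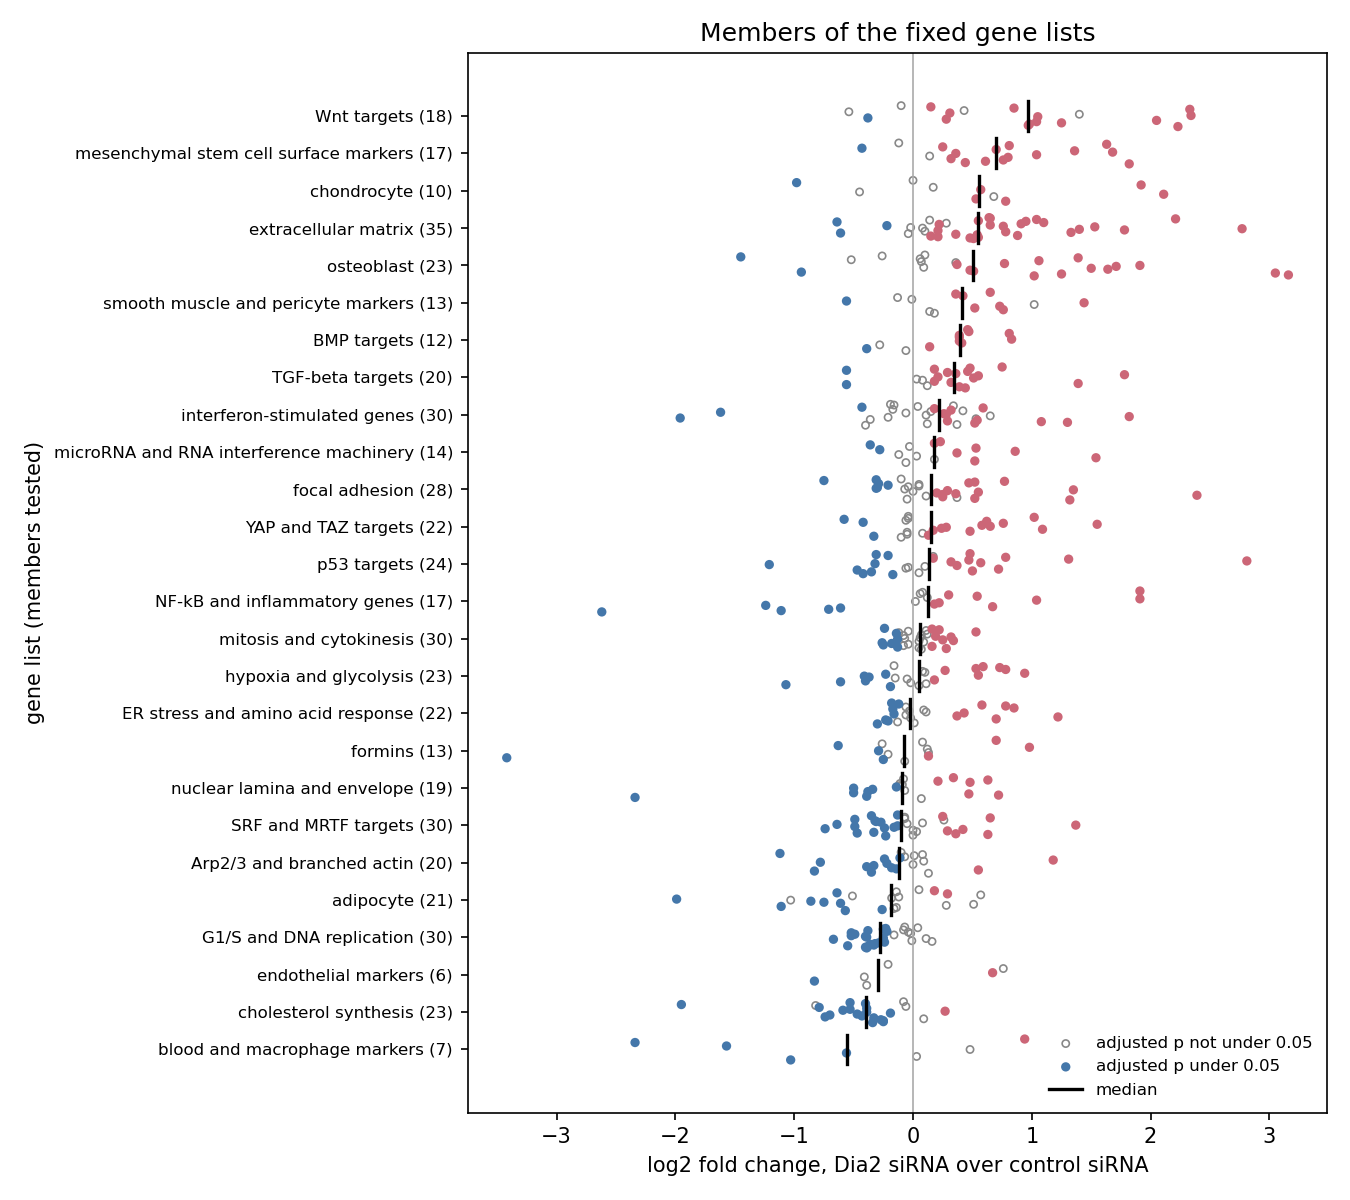
Log2 fold changes (Dia2 siRNA over control siRNA, horizontal axis) of the tested members of 26 gene lists, ordered by median, with the number of members tested in brackets. Filled points passed an adjusted p of 0.05, red for higher and blue for lower; open points did not, and black bars are medians, from 0.971 for Wnt targets to -0.56 for blood and macrophage markers.

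Of the 27 lists tested with the preset correlation 12 passed, 9 upward and 3 downward, but none passed with a correlation estimated from the libraries. Other ways of splitting the same 6 libraries gave up to 10 lists at the preset value. Each of those splits mixes both siRNA groups unevenly and keeps part of their difference, so its lists do not measure false calls. Some genes belong to several lists, such as Col1a1 in the osteoblast, extracellular matrix and TGF-beta lists, so the lists are not separate results. The counts of members above rest on the test of each gene and not on that correlation.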

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

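Halved counts, the fits without Rn45s and Lars2 or without the libraries richest in Rn45s, the GC and length offsets and the fit without genes holding the 3′ UTR words were chosen after seeing the data; the other settings were fixed before. Diaph3 stayed between -3.48 and -3.39 on the log2 scale without each library in turn and passed the threshold under every setting run. The number of genes changed, 8380 of 14151, lay between 7343 and 9193 without each library in turn, with 3651 to 4512 higher and 3677 to 4681 lower, and between 7747 and 8984 under the other settings, except for 6696 at an adjusted p of 0.01 and 5940 of 10437 genes without those holding the words. Genes changed at least 2-fold, 1214 by default and 1136 to 1305 without each library in turn, numbered 693 with a mean CPM of at least 1 and 768 without the genes holding the words, both of which test fewer genes. Slightly more genes were lower than higher by default (4235 and 4145), but more were higher with upper-quartile factors (4543 against 3822) and with GC and length offsets (4651 against 3996). Of 8380 genes, 8271 were also called by DESeq2 and 8311 by limma-voom, all in the same direction.

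The gene lists were less stable. The 12 lists past the threshold became 0 with an estimated correlation, 23 with fry, which asks another question, 9 with limma-voom, 11 with GC and length offsets, 11 without the genes holding the words (focal adhesion lost its call, adjusted p = 0.0945) and 8 without the libraries richest in Rn45s; without each library in turn they numbered 8 to 13, with 8 without control replicate 3. The lists of focal adhesion, YAP and TAZ targets, chondrocyte and smooth muscle genes were those that lost their call without control replicate 3, at adjusted p-values of 0.209, 0.175, 0.126 and 0.0734. Of the lists reported here, 1 that had not passed changed direction under 1 setting: interferon-stimulated genes pointed down without the libraries richest in Rn45s (adjusted p = 0.996). The cause was not tested.

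Of 130 named genes reported, 122 kept their direction and side of the threshold under all settings that tested them. The other 8 were Adipoq, Bmp2, Cidec, Diaph1, Lmna, Mpeg1, Vwf and Was, of which all but Diaph1 and Lmna were below 5 CPM; none changed sign. Lmna passed only with GC and length offsets (0.12, adjusted p = 0.0213). The seed match shift was 0.059, and 0.073, 0.046 and 0.061 with the 6-base site, the sense strand and genes of at least 10 CPM.

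With the replicate number as a replicate block 7794 genes passed, 3874 higher and 3920 lower, and 12 lists; Bmp2 lost its call (adjusted p = 0.0504). The deviations of same-numbered libraries from their group means correlated at 0.00, 0.00 and -0.08, and 0 of 6 libraries correlated best with their own number, so the numbers were not read as pairs. Depth limits scarce genes such as Bglap, Bglap2 and Bmp2, with 0 to 26 counts in a library.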

Other observations

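The shift of genes with the seed site of the stated siRNA and the splits for genes changed were planned tests. The share of lower genes holding that site was not part of the plan. Chosen after the results were seen were the tests that rest on the word scan, the microRNA comparison and the splits for gene lists. So were the fits with GC and length offsets, without the Rn45s-rich libraries and without Rn45s and Lars2.

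Some genes stood apart in a single library. Sap30l lay at 246 CPM in Dia2 replicate 2 and at 18.7 to 20.6 CPM in the other 5 libraries, and Gm20594, Kmt5c, Csad and 0610012G03Rik were high in that library alone, at 203, 72.2, 118 and 117 CPM. B630019K06Rik reached 184 CPM in Dia2 replicate 1 against 4.1 to 5.02 elsewhere. Prickle1, a planar polarity gene, stood at 107 CPM in control replicate 3, at 18.4 and 17.3 in the other controls and at 7.95, 8.62 and 7.86 in the Dia2 libraries. These genes were chosen after their values were seen, as those at least 4-fold above the other libraries of their group.

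Short 3′ UTR words went with the direction of change. Of 213 genes at least 2-fold lower with a 3′ UTR and a mean CPM of at least 2, 132 (62.0%, Wilson interval 55.3 to 68.2) hold TATGTGA or ATGTGAA there, where genes not past the threshold and of like 3′ UTR length would give 28.2%. In the scan of 16289 words ATGTGAA had the lowest z (-15.9, 1905 genes) and TATGTGA the next (-13.11). The adjusted mean log2 change fell by 0.103, 0.251 and 0.315 with 1, 2 and 3 or more sites, and was 0.029 ± 0.011 (SE) for genes with the words in the coding sequence alone and 0.056 ± 0.006 for genes with neither. Lmnb1 holds TATGTGAA in its 3′ UTR and again over its stop codon. A fall at least as large as that of Lmnb1 was seen in 2 of 557 genes with TATGTGAA in the 3′ UTR, Lmnb1 among them, and in 16 of 10150 genes without it. Those 16 are not free of the shorter words. They include 8 genes with TATGTGA or ATGTGAA there: Acsl4, Marcksl1, Mbnl3, Mrap, Ppif, Rbm47, Rgs16 and Tmprss11f. They also include Prl2c2, Prl2c3 and Ptpn5, which hold neither. The 5 genes with TATGTGAA that fell at least 4-fold, named after their values were seen, are Lmnb1 (-2.34), Rpia (-2.36), Atp5f1 (-2.28), Umad1 (-2.1) and Sccpdh (-2.0). Of 345 genes at least 2-fold higher, 66 (19.1%, 15.3 to 23.6) hold GCAGTAC, where 5.9% would be given by 3′ UTR length, and 85 (24.6%, against 28.6% by length) hold TATGTGA or ATGTGAA. Fbn1, Exoc4, Pik3ip1, Dkk3, Alcam and Runx2 are among the holders of GCAGTAC. Of the 213 genes at least 2-fold lower, 13 (6.1%, against 5.9% by length) hold GCAGTAC. Among named genes, Plin4 and Diaph2 fell and hold it, and Tln2 and Cxcl12 rose and hold ATGTGAA.

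For the lower genes, the tables argue against silencing through the seed of the stated siRNA, since 14.1% of those at least 2-fold lower hold its site (at most 19.4% by the Wilson interval) where 3′ UTR length gives 19.2%. That share was not part of the plan. The planned test was the shift of genes with the site, which was 0.059, at percentile 26 of permuted words. This was barely over the bound of 25, and under it, at 19.2, with genes of at least 10 CPM. All permuted words shifted above 0 too, from 0.023 to 0.109, so the sign of the shift tells nothing about silencing and the shift alone does not decide. Higher activity of miR-23, whose 8-base site is AATGTGAA, is argued against as the whole cause only by an ordering. Genes with TATGTGAA alone (-0.235) were lower than genes with AATGTGAA alone (-0.144, itself below 0), with a difference of -0.092 (permutation p = 0.00578). TATGTGAA was picked from these same fold changes and genes are not independent, so this comparison is no independent test. A candidate explanation stays open for part of the 62.0% holding a word. It is a small RNA in the Dia2 libraries whose seed pairs with TATGTGA, such as an siRNA other than the stated one. Its ground is that ATGTGAA was lowest in a random part of the genes and again ranked 1 of 16023 words in the remaining genes (z = -11.88). Since 3′ UTR length alone gives 28.2%, it reaches only the excess, and which holders belong to that excess is not known. For the other 81 genes, which have neither word in the 3′ UTR, no test here decides. Diaph3 holds TATGTGAA in coding exon 22, at the end of CCATTTCCTGGTAGATGTATGTGAA (chromosome 14, 86852136 to 86852160, GRCm38, minus strand), where an siRNA could pair, although 10% of coding transcripts of like length hold the word too. The loss of Dia2 stays open as the biological explanation, and whether the fall of Lmnb1 follows from it or from such a small RNA is not decided by a comparison with 1 siRNA against Dia2.

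For the higher genes, GCAGTAC was the highest word in a random part of the genes and again the highest of 16023 words in the remaining genes (z = 6.29). A small RNA acting in the control libraries may account for part of the rises among the 19.1% that hold GCAGTAC. The control siRNA is a candidate source of such a small RNA. Because 3′ UTR length alone gives 5.9%, not every holder need be affected. For single holders such as Runx2 and Fbn1, and for the 279 genes without the word, no test here decides. Over all genes of the scan, other words such as GCAATAC (z = 6.78) and CAGTACA (z = 6.06) were also raised. CAGTACA overlaps GCAGTAC, with 227 genes holding GCAGTACA, and the scan was not run without the holders of GCAGTAC. The loss of Dia2 stays open for both sets.

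For the number of genes changed, a trend with GC content and coding length is argued against as the whole cause. With offsets for both, 8647 genes passed and 7632 of the 8380 were shared. For a few genes taking many of the counts, 8984 passed without the library of each group richest in Rn45s, and 7980 were shared. Rn45s was high in 1 library of each group, so dropping these libraries could not decide on such a cause. With Rn45s and Lars2 taken out of the counts, 8402 genes passed and 8267 of the 8380 were shared. These values argue against Rn45s and Lars2 as the whole cause. Other abundant genes were not addressed by these fits. Of the 10 splits of the 6 libraries into 3 and 3, 1 gave as many genes, the real one with 8380, and the highest of the others gave 0 by edgeR (44 to 303 genes at an unadjusted p under 0.05; other tools were not run on the splits), while for gene lists the real split gave 12 and the highest other 10, again 1 of 10 as large. So few splits cannot give a share under 0.05. Every other split also mixes both siRNA groups unevenly. This adds their difference to the spread within each side and leaves part of it between the sides. The other splits therefore do not show how many genes or lists would pass without a group difference. Without the genes holding the words, 5940 of 10437 passed, and a loss of Dia2 and other effects of the siRNAs both stay open for them.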
